A study of Sclerotinia sclerotiorum with 3 samples.

How the data were processed

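RNA was measured in hyphae of Sclerotinia sclerotiorum, the fungus that causes white mould and stem rot in many broad-leaved crops. The fungus had grown for 72 hours in the dark at 21 °C on potato dextrose agar, a rich plant-free medium. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was isolated with magnetic beads, and sequencing libraries followed a published preparation protocol. The 3 samples form 1 group of biological replicates, so no contrast between conditions was made.

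The authors deposited 1 table with 1 value per gene and library. The deposited values are FPKM (fragment counts scaled to transcript length and library depth) that had been rounded to whole numbers, so they were handled as a score with no count model. Per the submitters' processing notes, Trimmomatic, TopHat2 and Cuffnorm were used, and the notes give no versions. The genome build, the annotation and the scaling that Cuffnorm applied between libraries are not given in the sources used here. That the values are FPKM and not raw counts rests on the table's own description, on the tool named in the notes, and on the fact that the values of short genes fell on steps that shrank with gene length. Rounding hides any level below 0.5 FPKM, so a gene listed at 0 need not have been without reads. The columns are called invitro_0, invitro_1 and invitro_2 and the samples are numbered differently, so each column was taken as an unnumbered replicate. The number of columns not used was 0.

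The table held 14637 genes. Of these, 14636 locus tags matched a RefSeq gene table of assembly ASM14694v2 and 1 did not. The reference table gave lengths, biotypes and gene order. Its symbols repeat the locus tags, so the gene functions stated in the text are background from published work on this fungus and were not read from the files. Lists of genes by product name could not be run for the same reason. No coordinates are printed because the build of the deposited table is not stated. Lengths are spans of the gene models, with introns. Mitochondrial genes were not analysed here.

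A gene was called detected at an FPKM of 1 or more. Levels are given as the mean ± SD over 3 libraries. Log values are log2(FPKM + 1), a scale that understates differences between low genes. Genes were counted as differing between replicates when the highest and lowest library lay more than 2-fold apart with a pseudocount of 1, among genes with a mean FPKM of at least 1. Pairs of libraries were also compared by the SD of the log2 difference across genes. Before the data were examined, 5 lists of locus tags were fixed, covering virulence, signalling and development, RNA silencing, fungicide targets with reference genes, and targets of double-stranded RNA. Lists with at least 5 members were tested by setting the list median minus the median of all other genes against 10000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over the 3 lists tested. Genes are not independent replicates, so these p-values describe where a list lies among the genes of these libraries. After the table had been opened, 19 locus tags recalled from published work were looked up together with their values. All 19 are reported and none of the lists they form was tested, namely 6 polygalacturonases (among them SS1G_10167, which also belongs to the tested virulence list), 7 further published genes and 6 genes whose recalled identity was uncertain. The gene pairs whose ratios are given were also chosen after their values were seen. An exact sign-flip permutation test over 3 values cannot go below p = 0.25, so differences between 2 genes are given with their SD and without a test.

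The rule for named genes, fixed at the same time, took the 25 genes with the highest mean FPKM among genes detected in every library, every member of the lists, and the 5 genes with the largest SD of log2 values over replicates among genes with a mean FPKM of at least 10. Other genes named were chosen after their values were seen, and the text says so.

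The table carries no read totals, but relative depth could be recovered. A model of effective length with a mean fragment of 200 nt and an SD of 80 nt, the same shortest fragment in all libraries and 1 scale per library was fitted to genes of 150 nt or less. The form of this model was chosen after the data were seen: several fragment means, spreads and shortest lengths were tried by hand on the same table, as was the tolerance, before this form was kept. The fitted shortest fragment was 49 nt. All 196 values worth up to 10 fragments lay within 5% of a fragment from a whole number of fragments. At 200 random scales a median of 4.52% and at most 47.4% of values did. Because the model was tuned and fitted on these values, this is a description of the fit and not an independent test. The step sizes put the depth of invitro_1 at 1.06 times and that of invitro_2 at 1.79 times that of invitro_0. Absolute depth stays unknown. Values converted to fragments with this model are called fragment equivalents. For longer genes they are too high wherever introns add to the length. To see how many genes counting alone leaves at 0 in a library, the pooled fragments of each gene were dealt to the libraries by depth in 200 draws, with the same rounding and filter. Fragments were taken as independent singly or in units of 2, 5 or 10, since introns in the lengths and copies of a molecule lower the number of independent fragments. This test was chosen after the data were seen. Intervals on shares of values are exact binomial at 95% and cover counting error only.

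Adjacent genes were compared by rank correlation of mean log2(FPKM + 1) within 35 segments, inferred from the order and start positions in the reference table, against 1000 permutations of gene order. Trends of library differences with gene length were tested with 10000 permutations across genes. Genes are not independent replicates, so these p-values describe the genes of these libraries and do not test a difference between libraries. The alternatives tried were other detection thresholds, rescaling each library to the same sum or upper quartile, another pseudocount, filters on low values, random lists matched on length, and leaving out each library. A restriction to genes of 300 nt or more, a split at that length, restrictions on neighbouring pairs by length and distance, the count of genes 1.5-fold apart in 1 library, the stretches of genes listed at 0 and the count of genes with 20 or more fragment equivalents were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

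The scripts were tested on simulated data over 14636 genes. Fragment scales were recovered with an error of at most 0.167%. The list test called 8 of 200 unshifted lists of 14 genes, 75 of 200 lists shifted by 2 on the log2 scale and 163 of 200 lists shifted by 4. The order test gave a permutation p of 0.49 for a shuffled order and 0.005 for simulated neighbour correlation, the smallest value that its permutations allowed.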

Results

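To describe which genes this fungus used away from a host, transcript levels were measured in 3 libraries of hyphae grown on potato dextrose agar for 72 hours. The series was collected to find target genes for RNA interference, in which double-stranded RNA directs the breakdown of a matching messenger RNA. On average 9368 ± 278 of 14637 genes (SD, n = 3) were detected at an FPKM of 1 or more. The libraries invitro_0, invitro_1 and invitro_2 held 9089, 9370 and 9644 detected genes. The table gives no read totals, so absolute depth is unknown. Relative depth, estimated from the smallest steps in the values, was 1, 1.06 and 1.79. In all 3 libraries 8421 genes were detected, or 57.5% of the table, and 4186 genes (28.6%) were listed at 0 throughout. The remaining 13.9% were detected in 1 or 2 libraries only.

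Protein-coding genes made up all 8421 genes detected in every library. Of 187 nuclear tRNA genes, 11 had a value above 0 in any library, and 10 of those had it in 1 library alone. Among detected genes the median level was 23.0 ± 1.00 FPKM (SD, n = 3). Per library, 1858 ± 29.5 genes stood at 100 FPKM or more and 290 ± 15.7 genes at 1000 or more (SD, n = 3). Detection rose with the length of the gene model. In gene models under 150 nt 5.55% were detected in all libraries, whereas in those of 2000 nt or more 81.9% were. Genes listed at 0 throughout had a median length of 480 nt, compared with 1419 nt for genes detected in every library. A single fragment on a gene of 300 nt was worth 3.17 FPKM in invitro_0, 3.00 in invitro_1 and 1.77 in invitro_2. Detection of the shortest models could therefore rest on 1 fragment.

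**Figure D1:**
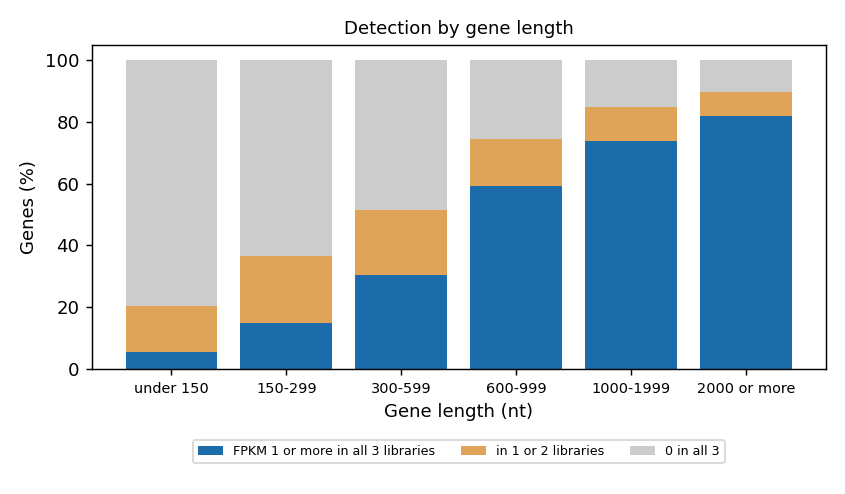
Share of genes (%) detected at FPKM 1 or more in all 3 libraries, in 1 or 2 libraries, or listed at 0 in all 3, by length of the gene model (nt). The share detected in all libraries rose from 5.55% under 150 nt to 81.9% at 2000 nt or more.

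The most abundant transcripts formed a steep top end. SS1G_00253 stood at 414311 ± 51436 FPKM (SD, n = 3) and held 16.0% ± 0.792 of the summed FPKM. The 100 most abundant genes of each library held 59.6% ± 1.61 (SD, n = 3). SS1G_00253 is a gene model of 123 nt, on which a single fragment was worth 72.6 FPKM in invitro_0, 68.5 in invitro_1 and 40.6 in invitro_2. By those steps its value corresponded to 6449, 5336 and 10085 fragments, or 0.118% ± 0.00898 (SD, n = 3) of all fragment equivalents, which placed it at rank 160. Introns in the lengths inflate the fragment equivalents of other genes, so the share and rank of SS1G_00253 may be too low. Without this gene the next 100 genes held 52.2% ± 1.49 of the remaining sum (SD, n = 3).

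The next genes by level were SS1G_03581 at 35419 ± 6605 FPKM, SS1G_12763 at 29482 ± 4232, SS1G_05520 at 28819 ± 1649, SS1G_01699 at 28454 ± 4382 and SS1G_09040 at 24650 ± 2115 (SD, n = 3). Then came SS1G_13124 at 22455 ± 3519, SS1G_06999 at 22133 ± 3240, SS1G_12077 at 21316 ± 3414, SS1G_01463 at 19671 ± 2008 and SS1G_09423 at 18674 ± 1208 (SD, n = 3). A further group lay between 14692 and 18605 FPKM, comprising SS1G_05038, SS1G_00066, SS1G_11139, SS1G_10336, SS1G_05283, SS1G_01873, SS1G_13910, SS1G_12183, SS1G_03351, SS1G_01679, SS1G_03527 and SS1G_04012. SS1G_10167 at 13739 ± 369 FPKM and SS1G_10627 at 13726 ± 2016 (SD, n = 3) closed the list of 25. Of these 25 genes, 23 were shorter than 1000 nt, and their median length was 551 nt. The difference between SS1G_10167 and SS1G_10627 was smaller than the SD of either. Over the 25 genes the median SD of log2 values was 0.19, and 21 of the 25 were highest in invitro_0. By fragment equivalents, SS1G_05520, a gene of 1892 nt, was at rank 1 with 3.18% ± 0.0707, and SS1G_10167 was at rank 3 with 0.845% ± 0.0572 (SD, n = 3). On that scale the 100 highest genes of each library held 41.2% ± 1.13 (SD, n = 3). Fragment equivalents are overestimates for genes with introns.

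Genes known for virulence were present at very different levels on the plant-free medium. SS1G_10167, published as polygalacturonase 1, a secreted enzyme that cuts pectin in plant cell walls, was at rank 24 of all genes. SS1G_08218, the oxaloacetate acetylhydrolase that makes oxalic acid, stood at 7697 ± 903 FPKM. The secreted protein gene SS1G_00263 stood at 3291 ± 633, and the cerato-platanin gene SS1G_10096, which encodes a small secreted protein, at 571 ± 88.7 (SD, n = 3). The integrin-like gene SS1G_14133 reached 232 ± 69.4 FPKM, the chorismate mutase gene SS1G_14320 reached 186 ± 41.2, and the appressorium gene SS1G_02486 reached 91.7 ± 6.43 (SD, n = 3). Lower levels were found for SS1G_07404 at 27.7 ± 1.53 FPKM, for the small secreted protein gene SS1G_02068 at 18.7 ± 5.03, and for SS1G_11912, necrosis and ethylene inducing protein 2, at 24.0 ± 5.57 (SD, n = 3). Its relative SS1G_03080, necrosis and ethylene inducing protein 1, was listed at 0 in all 3 libraries. The cyanovirin-N homology gene SS1G_02904 was listed at 0, 1 and 0.

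Of the 14 virulence genes, 12 were detected in every library and 3 stood above 1000 FPKM. The list median lay 3.34 above the median of all other genes on the log2 scale, or 3.24 ± 0.21 when computed library by library (SD, n = 3). It was higher than that of 99.8% of 10000 random lists (adjusted p = 0.015, two-sided permutation over random lists, Benjamini-Hochberg over 3 lists). The list stood above other genes in 3 of 3 libraries, but genes are not independent replicates. Other lists fixed beforehand also had medians above other genes, which was thus not particular to virulence. These were signalling and development (2.40), double-stranded RNA targets (3.36) and fungicide targets with reference genes (7.40). The RNA silencing list lay below other genes (-0.44). None of these passed the test or was long enough for it.

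**Figure D2:**
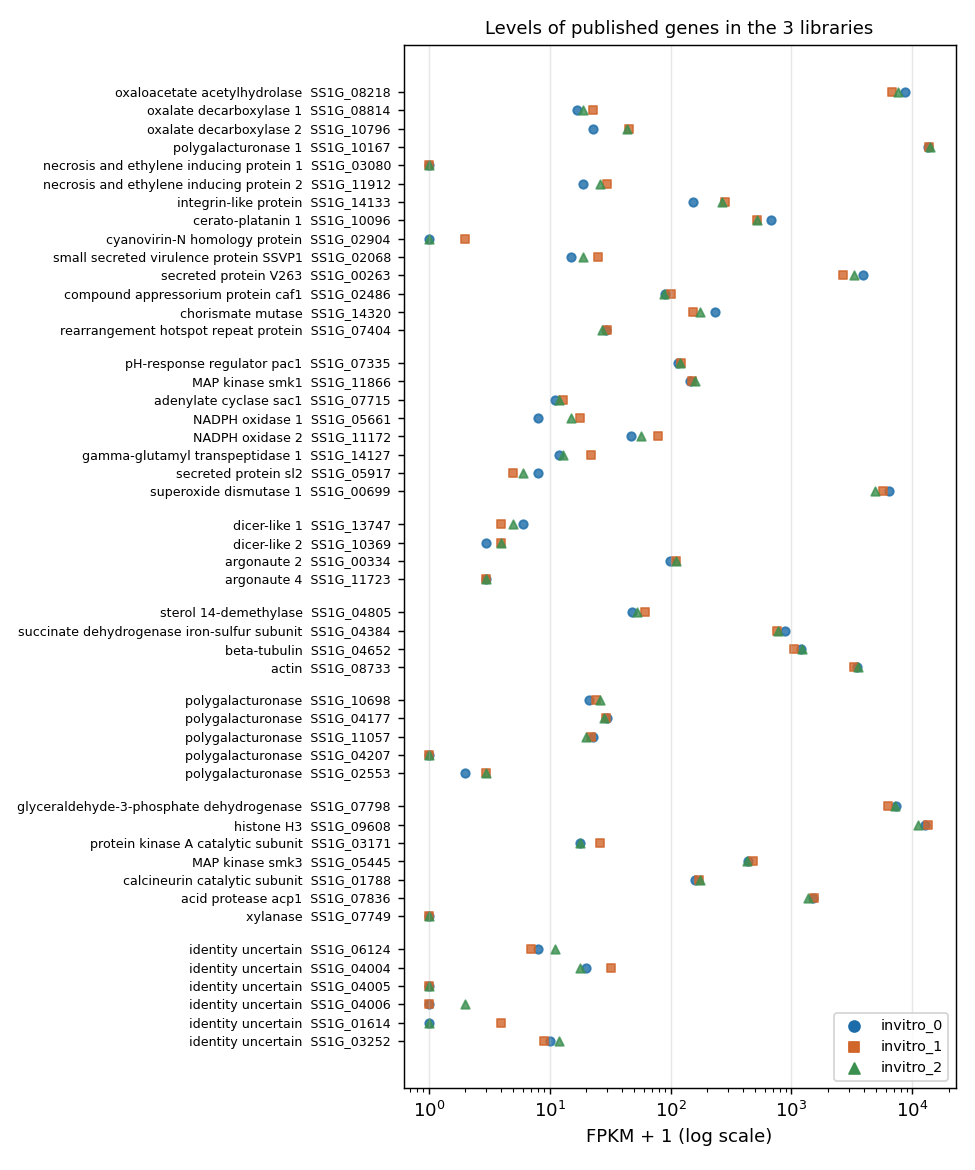
FPKM + 1 (log scale) of genes with published functions, with 1 point per gene and library; groups from top to bottom are virulence, signalling and development, RNA silencing, fungicide targets with reference genes, further polygalacturonases, further published genes and genes of uncertain identity. Polygalacturonase 1 stood at 13739 FPKM on average, the other polygalacturonases examined at 28 FPKM or less.

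Pairs of genes to set against each other were chosen after their values were seen. Polygalacturonase 1 stood 8.89 ± 0.09 log2 units above SS1G_04177, the next highest polygalacturonase examined, in 3 of 3 libraries (SD, n = 3). SS1G_04177 was at 28.0 ± 1.00 FPKM, SS1G_10698 at 22.7 ± 2.52, SS1G_11057 at 20.7 ± 1.53 and SS1G_02553 at 1.67 ± 0.577 (SD, n = 3). SS1G_04207 and the xylanase gene SS1G_07749, whose product acts on plant hemicellulose, were listed at 0 in all 3 libraries. The acid protease gene SS1G_07836 stood at 1470 ± 77.1 FPKM (SD, n = 3). Around oxalic acid, the synthetic gene SS1G_08218 stood 8.62 ± 0.39 log2 units above oxalate decarboxylase 1 (SS1G_08814, 18.7 ± 3.06 FPKM) and 7.75 ± 0.70 above oxalate decarboxylase 2 (SS1G_10796, 36.3 ± 12.4 FPKM). The decarboxylases break oxalate down. Decarboxylase 2 was above decarboxylase 1 in 3 of 3 libraries, by 0.87 ± 0.40 on the log2 scale (SD, n = 3). Other pairs examined were the MAP kinase genes SS1G_05445 and SS1G_11866, 1.57 ± 0.13 apart, actin (SS1G_08733) and beta-tubulin (SS1G_04652), 1.57 ± 0.07 apart, SS1G_11866 and SS1G_07335, 0.35 ± 0.07 apart, and SS1G_04384 and SS1G_04805, 3.90 ± 0.29 apart (log2, SD, n = 3).

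Signalling and development genes were all detected in every library, with 3 of the 8 at 100 FPKM or more. Superoxide dismutase 1 (SS1G_00699), which removes superoxide, stood at 5682 ± 747 FPKM. The MAP kinase gene smk1 (SS1G_11866) stood at 151 ± 7.55, and the pH regulator pac1 (SS1G_07335) at 118 ± 3.51 (SD, n = 3). NADPH oxidase 2 (SS1G_11172) at 60 ± 16.4 FPKM lay 2.20 ± 0.32 log2 units above NADPH oxidase 1 (SS1G_05661) at 12.7 ± 5.13, in 3 of 3 libraries. Both enzymes make superoxide. Gamma-glutamyl transpeptidase 1 (SS1G_14127) was at 14.7 ± 5.51 FPKM, adenylate cyclase (SS1G_07715) at 11.0 ± 1.00 and the secreted protein gene sl2 (SS1G_05917) at 5.33 ± 1.53 (SD, n = 3). The list median lay 2.40 above that of other genes on the log2 scale and did not pass the test (adjusted p = 0.15, two-sided random-list permutation). How often the test would call such a shift in a list of 8 genes was not checked. Among genes with a mean FPKM of at least 1, the shift was 0.46 (adjusted p = 0.65, two-sided random-list permutation). In this list 6 of 8 genes were lowest and 2 highest in invitro_0. Among further kinase and phosphatase genes, the MAP kinase gene smk3 (SS1G_05445) stood at 449 ± 29.4 FPKM, calcineurin (SS1G_01788) at 168 ± 7.77 and the protein kinase A catalytic subunit (SS1G_03171) at 19.7 ± 4.62 (SD, n = 3).

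The RNA silencing genes, which process double-stranded RNA, were detected in each library, and 1 of the 4 stood out in level. Argonaute 2 (SS1G_00334), of the protein family that carries the guide RNA, was at 106 ± 7.23 FPKM. Argonaute 4 (SS1G_11723) was at 2 in each library. Dicer-like 1 (SS1G_13747), of the family that cuts double-stranded RNA, was at 4 ± 1 FPKM and dicer-like 2 (SS1G_10369) at 2.67 ± 0.577 (SD, n = 3). Argonaute 2 exceeded argonaute 4 by 5.16 ± 0.10 log2 units, dicer-like 1 by 4.44 ± 0.38 and dicer-like 2 by 4.88 ± 0.14, each in 3 of 3 libraries (SD, n = 3). The list had a median of 3.33 FPKM and was too short to be tested against random lists. Rounding to whole FPKM limits the precision of the 3 low genes.

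Genes that have been targeted with double-stranded RNA in published work on this fungus were all detected in every library. SS1G_05899 was the highest of the 5 at 261 ± 31.1 FPKM. SS1G_06487 stood at 84.7 ± 9.82, SS1G_02495 at 59.7 ± 16.6, SS1G_01703 at 44.0 ± 6.93 and SS1G_11912 at 24.0 ± 5.57 (SD, n = 3). SS1G_05899 lay 2.55 ± 0.40 log2 units above SS1G_01703 in 3 of 3 libraries. The list median lay 3.36 above that of other genes on the log2 scale, a difference that did not pass the test (adjusted p = 0.14, two-sided random-list permutation). That shift was close to the 3.34 of the virulence list, which held 14 genes and passed. How often the test would call such a shift in a list of 5 genes was not checked. These targets may have been chosen with the help of these libraries, so the list is not independent evidence.

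Fungicide targets and common reference genes had a median of 985 FPKM and were too few to be tested. Actin (SS1G_08733) stood at 3447 ± 115 FPKM and beta-tubulin (SS1G_04652), the target of benzimidazole fungicides, at 1161 ± 95.1 (SD, n = 3). The iron-sulfur subunit of succinate dehydrogenase (SS1G_04384) was at 809 ± 68.1 and sterol 14-demethylase (SS1G_04805), the target of azole fungicides, at 53.3 ± 7.09 (SD, n = 3). Glyceraldehyde-3-phosphate dehydrogenase (SS1G_07798), a glycolytic enzyme, reached 6960 ± 575 FPKM, and histone H3 (SS1G_09608) reached 12429 ± 1248 (SD, n = 3). Polygalacturonase 1 exceeded actin by 1.99 ± 0.06 log2 units in 3 of 3 libraries (SD, n = 3). Of 6 further genes that were looked up and whose identity was uncertain, SS1G_04004 stood at 22.3 ± 7.57 FPKM, SS1G_03252 at 9.33 ± 1.53 and SS1G_06124 at 7.67 ± 2.08 (SD, n = 3). SS1G_01614 was listed at 0, 3 and 0, SS1G_04006 at 0, 0 and 1, and SS1G_04005 at 0 throughout.

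Replicates lay closer together for abundant genes than for low ones. Among 9548 genes with a mean FPKM of at least 1, 1779 (18.6%) differed by more than 2-fold between the highest and lowest library. That share was 40.2% between 1 and 10 FPKM, 10.2% between 10 and 100, 4.25% between 100 and 1000, and 1.76% (5 of 284 genes) at 1000 or more. The median SD of log2 values fell from 0.43 in the lowest class to 0.13 between 100 and 1000 FPKM and was 0.14 at 1000 or more. Across genes, Pearson's r of log2 values lay between 0.905 and 0.911 for the 3 pairs and Spearman's rho between 0.910 and 0.918. These correlations are across genes, which are not independent replicates. With 2 libraries compared in place of 3, 1066 genes differed by more than 2-fold without invitro_0, 1182 without invitro_1 and 1220 without invitro_2.

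The genes with the largest replicate spread were very short. SS1G_06346 (93 nt) was listed at 1000, 0 and 0 FPKM in invitro_0, invitro_1 and invitro_2. SS1G_11743 (96 nt) was listed at 860, 0 and 0, SS1G_03668 (93 nt) at 0, 472 and 0, SS1G_10641 (105 nt) at 0, 270 and 558, and SS1G_09779 (117 nt) at 358, 0 and 0. The highest of these values corresponded to 4 fragments, and the 558 FPKM of SS1G_10641 to 7. The 472 FPKM of SS1G_03668 and the 270 FPKM of SS1G_10641 each corresponded to 2 fragments.

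**Figure D3:**
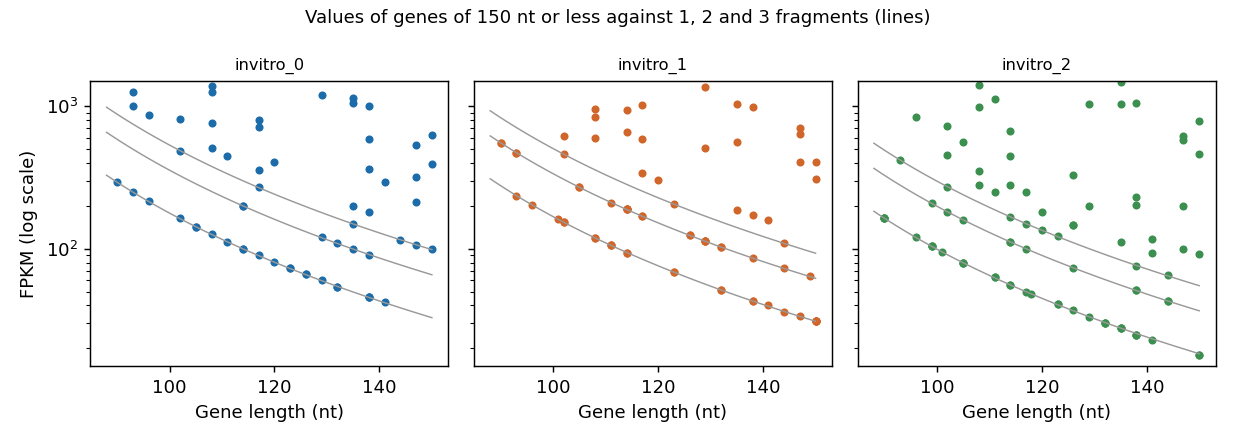
FPKM (log scale) of gene models of 150 nt or less against length (nt), with 1 panel per library and 1 point per gene; grey lines give the fitted value of 1, 2 and 3 fragments, and values beyond the top of the axis are not drawn. All 196 values worth up to 10 fragments lay within 5% of a whole number, and the lines sit lowest in invitro_2, the deepest library.

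Levels in invitro_0 relative to the other 2 libraries were lower in longer gene classes. Among 6240 genes with a mean FPKM of at least 10 and no 0, the median log2 difference was 0.16 under 600 nt, 0.14 from 600 nt, 0.05 from 1000 nt and -0.03 at 2000 nt or more. The quartiles spanned 0 in each class. Spearman's rho with length was -0.23 across genes (permutation p = 1e-04, the smallest the permutations can give). The permutation treats genes as independent, which they are not, so the p-value does not test a difference between libraries. In invitro_2 the same measure had a rho of 0.22 and in invitro_1 of 0.03. Each library was set against the other 2, so these values are not independent, and which library departs cannot be told from 3. Among published genes in the class from 1000 nt, the integrin-like gene SS1G_14133 was at 152 FPKM in invitro_0 against 279 and 264 in the others. Oxalate decarboxylase 2 (SS1G_10796) was at 22 against 44 and 43, and NADPH oxidase 1 (SS1G_05661) at 7 against 17 and 14. Others of that class were higher in invitro_0, such as SS1G_02495 (1993 nt) at 75 against 42 and 62 and SS1G_05899 (1328 nt) at 296 against 236 and 252. The median of the class was 0.05, and genes of a single class cannot show a trend with length. Of the 14 virulence genes, 6 were lowest and 4 highest in invitro_0. Of 5444 genes of 600 nt or more with a mean FPKM of at least 10 and no 0, 127 lay more than 1.5-fold below both other libraries in invitro_0, compared with 45 in invitro_1 and 28 in invitro_2. The numbers more than 1.5-fold above both others were 47 in invitro_0, 47 in invitro_1 and 22 in invitro_2. These counts were chosen after the values were seen, and no test between libraries was made.

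**Figure D4:**
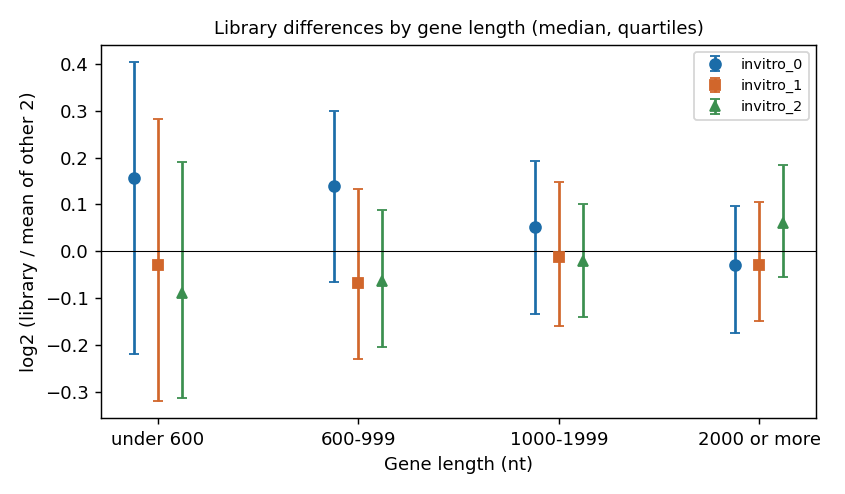
Log2 difference of each library from the mean of the other 2 by length class of the gene model (nt), for 6240 genes with a mean FPKM of at least 10; points are medians and bars span the quartiles. The median of invitro_0 went from 0.16 under 600 nt to -0.03 at 2000 nt or more.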

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

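The restriction to genes of 300 nt or more and the restrictions on neighbouring pairs were chosen after the data were seen. Of 60 alternative settings of 8 main results, 48 kept the direction and the side of the threshold, or stayed within the replicate SD (for counts, within 1.5-fold), 12 moved a value and 0 reversed one. The share of summed FPKM in the 100 most abundant genes moved from 59.6% to 52.2% without the most abundant gene and to 53.7% with genes of 300 nt or more. The number of genes more than 2-fold apart moved from 1779 to 544 with a mean FPKM of at least 10 and to 1142 with each library rescaled to the same sum. Rescaling let fewer genes pass the filter and also made values smaller beside the fixed pseudocount. The number was 1066 without invitro_0, 1182 without invitro_1 and 1220 without invitro_2, where 2 values per gene were compared and not 3. The mean SD of log2 differences moved from 1.13 to 1.92 with a pseudocount of 0.1, 1.02 with a mean FPKM of at least 10, 0.939 with no filter, 0.862 after rescaling to the same sum and 0.79 with genes of 300 nt or more. It ranged from 1.11 to 1.18 with each library left out in turn. A spread taken from the median absolute deviation, which extreme genes move less, was smaller at a mean FPKM of at least 1. It was 0.39 between invitro_0 and invitro_1, 0.37 between invitro_0 and invitro_2, and 0.32 between invitro_1 and invitro_2. For these moves of the share, of the number of genes after rescaling and of the SD the cause was not tested. The detection threshold of 0.1 FPKM could change nothing, since the values are whole numbers, and 5 FPKM gave 7516 detected genes. For the virulence list the log2 difference ranged from 2.58 to 3.68 and the adjusted p from random-list permutation from 0.0084 to 0.036 over the alternatives; the signalling list and the double-stranded RNA targets passed in none. The neighbour correlation ranged from 0.13 to 0.27 and passed in each alternative run. Splitting neighbouring pairs by strand, and leaving out tandem copies by product name, were not run because strand and product were not in the tables used. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, so for the number of detected genes, the share and the named genes those settings say nothing of stability. Of the 81 named genes, 8, each listed at 0 in some library, moved by more than 1.5-fold in some setting. Rounding to whole FPKM and unknown absolute depth limit what can be said of genes under about 1 FPKM.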

Other observations

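The tests on few fragments and on counting alone in genes listed at 0 in a library, on neighbours by distance and by gene length, on stretches of genes listed at 0, on the length trend and on the spread of the virulence list were chosen after the pattern they address had been seen; the neighbour correlation itself was fixed earlier. Neighbouring genes tended to stand at similar levels. Across 14601 adjacent pairs, Spearman's rho of mean log2(FPKM + 1) was 0.28 (permutation p = 0.001, the smallest 1000 permutations can give), against a highest permuted value of 0.037. It was 0.26 in each library alone, and fell to 0.13 for genes 2 places apart, 0.07 for 3 places and 0.03 for 10 places. The correlation was 0.53 for 231 pairs at most 200 nt apart or overlapping, 0.39 for 7298 pairs over 200 and up to 1000 nt apart and 0.13 for 7072 pairs over 1000 nt apart. The longest stretches listed at 0 in all 3 libraries were 2 of 15 genes, from SS1G_10026 to SS1G_14631 (median length 100 nt) and from SS1G_08012 to SS1G_08026 (median length 813 nt), which are named because of their values. The longest stretch in 1000 permuted orders held 14 genes (permutation p = 0.001). In the stretch from SS1G_08012 to SS1G_08026, 7 genes were 1000 nt or longer. The stretch from SS1G_10026 to SS1G_14631 held 1 such gene. Of all gene models under 150 nt, 79.7% were listed at 0 in all 3 libraries, so a run of short models at 0 is less remarkable.

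A pair of technical explanations for the neighbour pattern was tested. Reads shared between genes that overlap or nearly touch would leave little correlation in distant pairs, but pairs over 1000 nt apart kept a rho of 0.13, above the 0.038 of any permuted order. Stretches of short models listed at 0 are also argued against as the whole cause, since genes of 600 nt or more kept a rho of 0.22. There each gene was paired with the next one left after shorter genes were dropped, so some pairs were not adjacent. With only genes of 600 nt or more that were detected in every library, paired in the same way, rho was 0.11. Both may still contribute, as the correlation was strongest at short distance, and no biological explanation was tested.

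High values beside a 0 were examined by gene length. Over all 239 genes with a mean FPKM of at least 10 and a 0 in some library, 50.9% of nonzero values were worth at most 3 fragments (95% exact interval 45.5 to 56.2), and the genes were then divided at 300 nt. In genes of 300 nt or more, values of at most 3 fragments alone reach a summed FPKM of at most 21.6, below the 30 that the filter needs. The filter therefore holds down the share over all 239 genes, and the share cannot contrast the length classes. In the 188 shorter genes, 177 of 270 nonzero values were worth at most 3 fragments, or 65.6% (interval 59.6 to 71.2), in line with counting noise on a short effective length. Counting alone gave 131 such genes on average and at most 146 in 200 draws, and 177 on average and at most 192 with fragments independent in pairs, so whether it could account for all 188 stays open. Over 109 to 123 gene models of 250 nt or less, chi-square per degree of freedom between libraries was 4.03 to 7.32, a spread that holds differences between cultures as well as counting error. In the 51 genes of 300 nt or more, counting alone gave 0.06 genes on average and at most 1 in any draw. It gave at most 7 with fragments independent in pairs and at most 44 in units of 5. In units of 10 it gave 118 on average and at least 93, more than the 51 seen. How many fragments were independent was not measured, so counting noise stays open for these genes too. SS1G_11368, a gene of 909 nt, was listed at 0, 0 and 327 FPKM, or about 1305 fragment equivalents in invitro_2, while the genes on either side held 13, 15 and 18 FPKM (SS1G_11367) and 184, 217 and 199 FPKM (SS1G_11369). In all, 174 genes were at 0 in a library and at 20 or more fragment equivalents in another, of which 130 were at 0 in invitro_0, 85 in invitro_1 and 38 in invitro_2. A single fragment rounds to 0 from a length of 837 nt in invitro_0, 802 nt in invitro_1 and 558 nt in invitro_2. The counts were not adjusted for depth, so they cannot be compared between libraries. SS1G_11368 is named because of its values, and no cause other than counting was tested.

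The trend of invitro_0 with gene length was weighed against 2 technical explanations. Counting noise in a shallower library falls on low and short genes, but among 942 genes of 1000 nt or more at a mean FPKM of 100 or more, rho with length was -0.30 (permutation p = 1e-04). The rho over all 6240 genes was -0.23 in invitro_0, 0.03 in invitro_1 and 0.22 in invitro_2, which is the order of their depth (1, 1.06 and 1.79). The sizes did not follow depth, as invitro_0 and invitro_1 were close in depth and far apart in rho. A difference tied to depth other than counting noise stays open. A difference tied to abundance alone is argued against by the partial rank correlation with length at fixed mean FPKM, which was -0.18 (permutation p = 1e-04). The partial rank correlation with mean FPKM at fixed length was 0.13 (permutation p = 1e-04), so abundance had a trend of its own. Among 881 genes under 1000 nt at a mean FPKM of 100 or more, rho with length was -0.02 (permutation p = 0.49). In these 881 genes rho with mean FPKM was 0.11 (permutation p = 0.0012). RNA integrity, fragment size or growth state may differ between the libraries; none was tested.

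The virulence list spanned a wide range. The SD of log2 levels over its 13 members detected in some library was 3.88, at the 97.4th percentile of random lists of detected genes, whose median was 2.58. This lay inside the middle 95% of random lists (1.67 to 3.90), so a spread of this size could be chance.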
